A study of Mus musculus with 6 samples.

How the data were processed

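RNA was measured in preparations of isolated glomeruli, the filtering units of the kidney, taken from 3-week-old mice. Transcripts of kidney tubules were also present in every library. A series of 6 libraries was used, 3 labelled CTRL with a wild type genotype and 3 labelled KO with a podocyte-specific loss of bPIX, each library from 1 mouse. bPIX is the protein encoded by Arhgef7, an exchange factor for the small GTPases Cdc42 and Rac1, and podocytes are the epithelial cells that cover the glomerular capillaries. Libraries are named here by group and animal number as the sample labels give them. The names of the deposited files carry the other group for all 6 libraries, so that each file deposited under a sample labelled CTRL is named for a KO animal and the reverse. Groups were taken from the sample labels and not from the file names. If the file names were right and the labels wrong, every difference reported here would have the opposite sign and the same size.

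Per the labels, total RNA was extracted from isolated glomeruli with a column kit. The isolation method is not given in the sources used here. Per the submitters' processing notes, fastp 0.19.5, STAR 2.6.0, HTSeq 0.11.1 and DESeq2 were used, with no version for DESeq2 and no statement of which step each tool served. The same notes list the build GRCh37, a human assembly, while all gene identifiers in the deposited files are mouse Ensembl identifiers, so the build used for alignment is uncertain. The annotation release, the strand setting and the rule for reads that align to several places are not given in the sources used here. Without a known strand setting, reads of overlapping genes on opposite strands cannot be assigned to one of them.

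The deposited values are raw read counts per gene, whole numbers with no normalization, in 1 file per library with 54838 gene identifiers. Each file ends with 5 lines that name no gene. These lines were left out of library sizes and tests. Their shares of all counted records were 2.57% to 3.41% for reads in no annotated feature, 1.55% to 1.79% for ambiguous reads, 0.13% to 0.15% for low alignment quality, 0.7% to 1.22% for unaligned reads and 22.51% to 29.63% for reads that aligned to more than 1 place. Reads of the last kind are absent from the gene counts, so genes with near-identical copies are undercounted.

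Gene names, types and positions came from GENCODE M21, a mouse annotation on GRCm38, matched by identifier with the version removed. Of the identifiers, 54723 were named and 115 were absent from that annotation. The unnamed identifiers held at most 0.031% of gene counts in any library. Positions printed here are those of the annotation on GRCm38 and not of the deposited files.

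Gene counts totalled 45479480, 39841396 and 46187515 in the libraries labelled CTRL (157, 162 and 163), and 51917945, 40246366 and 46286734 in those labelled KO (146, 147 and 148). Before replicates were averaged, their counts were compared by a chi-square test over genes with at least 50 summed counts. The statistic per degree of freedom was 16.7 or more for each pair within a group, far above 1, so no library was taken as a second copy of another.

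The analysis ran in R 4.3.3. The counts were tested with edgeR 4.0.16, using TMM normalization, the filterByExpr filter by group with a minimum count of 10, and the robust quasi-likelihood F test of libraries labelled KO against those labelled CTRL with no covariate. P values were adjusted over all tested genes by the Benjamini-Hochberg method, and genes with an adjusted p below 0.05 were called. Standard errors are the absolute log2 fold change divided by the square root of F. Expression levels are given as CPM, the counts scaled by TMM library sizes, and log values for list means used a prior count of 2. A set of 24 gene lists, covering renal and blood cell types, the PIX complex, the cytoskeleton, stress responses and metabolism, was written before the data were examined. The lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated, and with fry. Adjusted p values of list tests are Benjamini-Hochberg values over the 24 lists. Members are counted by the adjustment over all tested genes and also adjusted over the list alone. Differences of single values between groups were tested by exact two-sided permutation of the 6 libraries, which cannot give a p below 0.1.

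The genes named were set by a rule fixed before the data were examined. It took 9 genes in every case, of which Arhgef7, Nphs1, Wt1, Synpo, Podxl, Ccn1, Ccn2 and Ankrd1 are reported and 1 is not reported here. It added the 8 largest rises and 8 largest falls among called protein-coding genes with separated groups and a mean of at least 5 CPM in the higher group. It also took the 3 members with the smallest adjusted p from each list that camera called or that held at least 3 called members. Genes outside the rule are marked as chosen after their values were seen.

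Alternatives set before the data were examined were DESeq2 size factors (RLE) or library totals in place of TMM, DESeq2 1.42.0 and limma-voom in place of edgeR, no filter, a filter of at least 1 CPM in 3 libraries, a 2-fold minimum, the mean of the proximal tubule list as a covariate, and each library left out in turn. Chosen after seeing the data were a covariate made of the glomerular endothelial and mesangial list means, and a restriction to protein-coding genes. Neither covariate overlapped between the groups, so every value given with a covariate rests on an extrapolation between them. Parent genes of pseudogenes were found by aligning the pseudogene sequences to the annotated transcripts with blastn 2.17.0. Plots were drawn with matplotlib 3.10.9.

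The tests were first run on simulated counts for this comparison of 3 against 3 libraries, with 100 genes changed 2-fold and 100 changed 4-fold. Over 16879 genes, edgeR recovered 63% of the 2-fold and 100% of the 4-fold changes, with 18 false among 181 calls. On the same counts, limma-voom recovered 57% and 99%, with 11 false among 167 calls. Over 17086 genes, DESeq2 recovered 81% and 100%, with 77 false among 258 calls. In that simulation, 2 of 100 unchanged lists passed an unadjusted camera p of 0.05. Genes were drawn independently there, so this check does not cover genes or lists whose members move together. Its recovery and false call rates therefore do not carry over to such genes. In the real data the podocyte list had a median log2 fold change of 2.0 with 0 of 36 members called by edgeR. In the real data the estimated correlation was 0.857, 0.979 and 0.966 for the podocyte, endothelial and mesangial lists.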

Results

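Gene expression was measured by RNA sequencing in isolated glomeruli of 3-week-old mice, in 3 libraries labelled CTRL and 3 labelled KO. The design set glomeruli of control mice against those of mice lacking bPIX (Arhgef7) in podocytes, and so asks which transcripts differ when podocytes lack this Cdc42 and Rac1 exchange factor. Gene counts ranged from 39841396 to 51917945 per library, and 24893 to 27767 genes were detected per library. Tubule transcripts were abundant in every library. The proximal tubule list mean was 10.31 log2 CPM in the libraries labelled CTRL and 9.7 in those labelled KO. The podocyte list mean was 5.26 and 6.75. A difference between the groups can therefore arise in tubule cells as well as in glomerular ones. Mitochondrially encoded genes held 16.54% to 18.21% of the counts in the libraries labelled CTRL, and 11.94%, 17.15% and 19.25% in KO 146, 147 and 148. The 3 libraries labelled CTRL were close to each other, with a Pearson r across genes of 0.992 for each pair. Among those labelled KO, r lay between 0.969 (146 and 148) and 0.991 (147 and 148), where genes are not independent replicates. The first principal component held 68.8% of the variance and placed the libraries labelled CTRL between -42.3 and -34.7, KO 148 at 3.5, KO 147 at 26.1 and KO 146 at 82.7.

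The targeted gene did not separate the groups. Arhgef7 (ENSMUSG00000031511, chromosome 8, 11727721 to 11835219, plus strand, GRCm38) was counted 3956, 3582 and 3915 times in CTRL 157, 162 and 163, and 7837, 3712 and 3903 times in the libraries labelled KO 146, 147 and 148. Its level was 91.5 ± 2.83 CPM in the libraries labelled CTRL and 103 ± 26.1 CPM in those labelled KO (SD, n = 3 each). The log2 fold change, labelled KO minus labelled CTRL, was 0.17 (SE 0.17, edgeR Benjamini-Hochberg adjusted p = 0.544). It was -0.07 without KO 146 and -0.42 with proximal tubule content as a covariate (edgeR adjusted p = 0.0704, range over all alternatives 0.0704 to 0.733). A podocyte-only deletion leaves the gene intact in other cells, and counts over the whole gene do not isolate a deleted exon, so this value does not settle the genotype labels. The names of the deposited files carry the other group for all 6 libraries, and every direction given here rests on the sample labels.

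Among the called genes of largest change, several mitotic genes were higher and several cytochrome P450 genes were lower in the libraries labelled KO. No list of cytochrome P450 genes was tested. Of 17086 genes tested, 173 were called, 101 higher and 72 lower, of which 156 were protein-coding and 131 differed at least 2-fold. Values and calls given to edgeR are those of the fit to all 6 libraries unless a change is named. Among called protein-coding genes with a mean of at least 5 CPM in the higher group, the rises of greatest size were those of Ntrk2, the receptor for brain-derived neurotrophic factor (log2 fold change 2.98, SE 0.42), and Adam12, a membrane metalloprotease (2.76, SE 0.40). Next came Slfn9 at 1.98 (SE 0.25), Boc, a co-receptor of hedgehog signalling, at 1.87 (SE 0.27), and the mitotic genes Prc1, Aspm, Cenpf and Espl1 at 1.6, 1.58, 1.56 and 1.52. Prc1, which bundles microtubules of the central spindle, went from 3.48 ± 0.41 to 10.6 ± 0.28 CPM (SD, n = 3 each). Among the same set of genes the deepest falls were those of the cytochrome P450 genes Cyp2a4 (-2.88, SE 0.34), Cyp4a12a (-2.79, SE 0.37) and Cyp2d9 (-2.74, SE 0.37). Car3, a carbonic anhydrase, fell by 2.21 on the log2 scale, and Hpd, an enzyme of tyrosine breakdown, went from 33.6 ± 5.02 to 8.96 ± 0.91 CPM (log2 fold change -1.90, SE 0.14). Cyp2a5, Cyp4a31 and Eci3, an enoyl-CoA isomerase, changed by -1.79, -1.76 and -1.65. These 16 genes had edgeR adjusted p values between 0.00891 and 0.0499, and in all 173 calls the 3 libraries of 1 group lay above the 3 of the other. Cyp2a4, Cyp2a5, Cyp4a12a and Cyp2d9 have close paralogs, so reads that align to several copies are missing from their counts. Tubule markers had lower and podocyte, endothelial and mesangial markers higher values in the same libraries. Of these, 1 tubule marker and 0 podocyte, endothelial or mesangial markers were called. None of their lists was called with an estimated correlation or by fry. With proximal tubule content as a covariate edgeR no longer called Ntrk2, Boc and Espl1 (1.79, 1.06 and 0.81) or Cyp2a4, Cyp4a12a, Cyp2d9, Car3, Cyp2a5 and Eci3 (-2.47, -1.78, -3.40, -1.28, -1.72 and -1.22), with adjusted p values from 0.0699 to 0.42, and still called the other 7. Over all alternatives the adjusted p of the 16 genes ran from 1.02e-23 to 0.455.

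The count of calls depended strongly on single libraries. It was 2, 3 and 10 without CTRL 157, 162 and 163, and 2974, 2 and 3211 without KO 146, 147 and 148, and DESeq2 called 2874 genes. An unadjusted edgeR p below 0.05 was reached by 5011 genes, and the groups did not overlap in 41.5% of tested genes, against 10% by chance for 3 against 3. The 10% holds for each gene alone. Genes moved together here, with 68.8% of the variance on the first principal component, so the excess by itself does not show a group effect. Scaling by library totals moved the median log2 fold change of all genes from -0.006 to 0.132 and the higher share of calls from 58.4% to 69.5%.

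Cell cycle genes had the most called members of any list in the edgeR fit to all 6 libraries, while DESeq2 called 30 podocyte markers and 25 cell cycle genes. Of 28 tested members, 16 were higher, 0 were lower and 12 did not pass, with 27 higher when adjusted over the list alone. The median log2 fold change was 1.16. Top2a, the topoisomerase that untangles replicated DNA (ENSMUSG00000020914, chromosome 11, 98992943 to 99024189, minus strand), rose from 10.3 ± 0.71 to 27.3 ± 0.96 CPM (SD, n = 3 each; log2 fold change 1.41, SE 0.092, edgeR adjusted p = 0.00612). Cenpf, a kinetochore protein, rose by 1.56 (SE 0.12, adjusted p = 0.00891) and Kif11, a motor of the mitotic spindle, by 1.31 (SE 0.12, adjusted p = 0.0225). The list mean was 2.81, 2.96 and 2.96 log2 CPM in CTRL 157, 162 and 163 and 3.84, 3.98 and 3.97 in KO 146, 147 and 148. Camera called the list (adjusted p = 1.08e-26), with an adjusted p = 0.124 with an estimated correlation. By fry the adjusted p was 0.00178. Leaving out CTRL 157, CTRL 162 or KO 147 left 0 members past the threshold in edgeR, leaving out CTRL 163 left 1, and leaving out KO 146 or KO 148 gave 25, while the median stayed between 1.07 and 1.23. The endothelial and mesangial marker means were also higher in the libraries labelled KO, at 7.18, 5.93 and 5.40 log2 CPM in 146, 147 and 148 against 4.65 to 4.75.

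**Figure D1:**
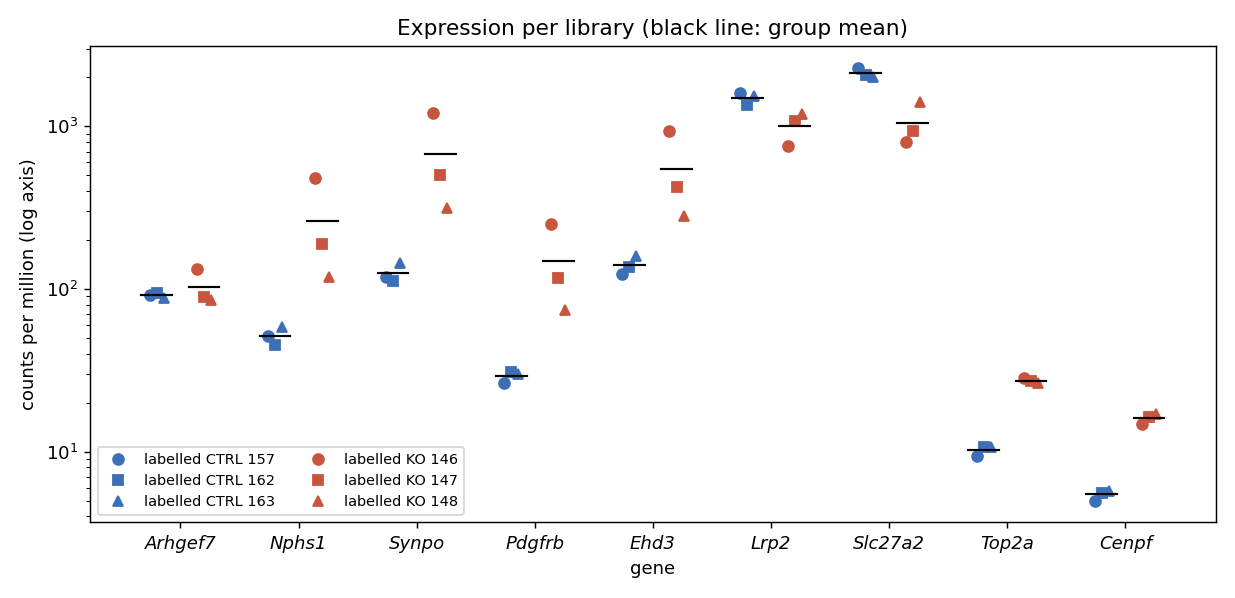
Normalised expression (CPM) of 9 genes in each library on a log axis, with libraries labelled CTRL in blue, those labelled KO in red and a black line at each group mean. Top2a and Cenpf form tight, separate groups, while Nphs1, Synpo, Pdgfrb and Ehd3 spread widely among the libraries labelled KO, with KO 146 highest, and Arhgef7 overlaps between groups.

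Markers of podocytes, glomerular endothelial cells and mesangial cells had higher values in the libraries labelled KO, with no single member past the threshold. Parietal epithelial markers were mixed, with 7 of 14 positive, a median of -0.002, a mean of 0.304 and 1 called. Their list mean did not overlap between the groups, at 3.82, 3.85 and 3.89 log2 CPM in CTRL 157, 162 and 163 and 4.08, 4.21 and 4.06 in KO 146, 147 and 148. Neither camera (adjusted p = 0.293) nor fry (adjusted p = 0.0981) called the list. Of 36 podocyte markers, 35 had a positive log2 fold change and the median was 2.0. Nphs1, which encodes the slit diaphragm protein nephrin, had a log2 fold change of 2.35 (SE 0.50). It stood at 51.5 ± 6.49 CPM in the libraries labelled CTRL and 263 ± 191 CPM in those labelled KO (SD, n = 3 each). The values were 2.05 for Wt1, the podocyte transcription factor, 2.43 for Synpo, an actin-associated protein, 2.10 for Podxl, a surface sialomucin, and 2.64 for Sema3g. Their edgeR adjusted p values lay between 0.0594 and 0.0772. All 25 glomerular endothelial markers were positive, with a median of 1.72, among them Plat (2.20), Emcn (1.74) and Ehd3 (1.98). All 21 tested mesangial and smooth muscle markers were positive, with a median of 1.67, among them Sfrp2 (2.47) and the growth factor receptors Pdgfrb (2.35) and Pdgfra (2.06). Of 16 genes of the glomerular basement membrane, 15 were positive with a median of 1.05, with Col4a1 at 1.35, Col4a2 at 1.39 and Lama4 at 2.26.

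For the podocyte, endothelial, mesangial and basement membrane lists, edgeR called 0 members in either direction over all tested genes. At an unadjusted p below 0.05, 32, 25, 20 and 13 members were higher, and 1 basement membrane member was lower. Adjusted over the list alone, 32, 25, 18 and 13 were higher and 1 basement membrane member was lower. DESeq2 called 30, 24, 17 and 11 members higher, and limma-voom called 0 in each. Camera called all 4 lists (adjusted p = 9.12e-16, 1.68e-12, 2.40e-10 and 2.36e-07), and each had an adjusted p = 0.488 with an estimated correlation and 0.159 by fry. The podocyte mean was 5.26, 5.13 and 5.38 log2 CPM in CTRL 157, 162 and 163 and 7.63, 6.53 and 6.10 in KO 146, 147 and 148. Without KO 146, edgeR called 32, 19, 17 and 11 members of the podocyte, endothelial, mesangial and basement membrane lists higher. The medians of these lists were then 1.24, 1.06, 0.77 and 0.63, with 20 of 21 mesangial markers positive. Without KO 148 edgeR called 32, 25, 17 and 12 higher, and with any other library left out 0. With proximal tubule content as a covariate the list medians were 0.22, 0.07, 0.06 and 0.06 and camera called the podocyte list alone (adjusted p = 0.0175, 0.905, 0.196 and 0.121). Over all alternatives these p values ran from 7.54e-37 to 0.488, 8.13e-23 to 0.905, 2.14e-17 to 0.666 and 6.88e-15 to 0.488. The 0.666 came from the covariate made of the endothelial and mesangial lists themselves, so that loss of the call was built in. Relative to the mean of the endothelial and mesangial lists, the podocyte mean was 0.54 ± 0.13 in the libraries labelled CTRL and 0.58 ± 0.13 in those labelled KO (SD, n = 3 each, exact permutation p = 0.7, smallest possible 0.1). Without the 5 podocyte markers that tubules also express, the same measure was 0.19 ± 0.15 and 0.38 ± 0.06 (exact permutation p = 0.1).

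Tubule markers had lower values in the libraries labelled KO. All 23 proximal tubule markers had a negative log2 fold change, with a median of -0.54. Slc7a13, an amino acid transporter, was the only one called by edgeR over all tested genes, and went from 380 ± 29.5 to 194 ± 22.8 CPM (SD, n = 3 each; -0.97, SE 0.12, adjusted p = 0.0332). The sulfate transporter Slc13a1 had a value of -0.88 and the fatty acid transporter Slc27a2 of -1.02 (edgeR adjusted p = 0.0755 for both). When adjusted over the list alone, 13 were lower. DESeq2 called 14 lower and limma-voom 1. With edgeR, 15 were called lower without KO 146, 5 without KO 148 and 0 with any other library left out. All 20 markers of the loop, distal tubule and collecting duct were negative as well, with a median of -0.42, including the water channels Aqp3 (-0.63) and Aqp2 (-0.52) and the anion exchanger Slc26a4 (-0.63). edgeR called 0 of these 20 over all tested genes, 1 was lower adjusted over the list alone, 9 were lower at an unadjusted p below 0.05, DESeq2 called 3 lower and limma-voom 0. Without KO 146 their median was -0.25, with 1 positive. Camera called both lists lower (adjusted p = 1.74e-11 and 4.44e-06), each with an adjusted p = 0.488 with an estimated correlation, and fry gave 0.148 and 0.159. With the endothelial and mesangial means as a covariate neither was called (adjusted p = 0.452 and 0.216, range over alternatives 4.99e-13 to 0.874 and 6.37e-07 to 0.488). The 0.874 came from the covariate made of the proximal tubule list itself, which removes that list's difference by construction. The proximal tubule mean was 10.4, 10.3 and 10.3 log2 CPM in CTRL 157, 162 and 163 and 9.28, 9.84 and 9.97 in KO 146, 147 and 148, so the library with the highest glomerular markers had the lowest tubule markers.

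**Figure D2:**
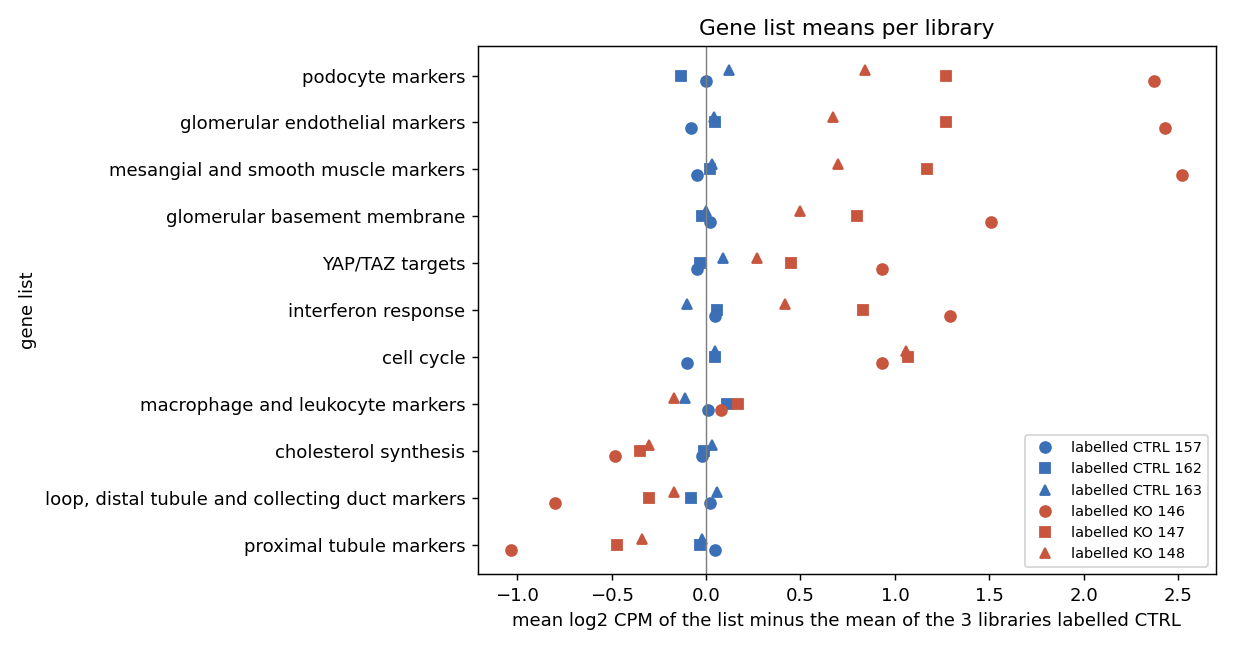
Mean log2 CPM of 11 gene lists in each library, as the difference from the mean of the 3 libraries labelled CTRL, shown in blue, with those labelled KO in red. Podocyte, endothelial and mesangial means are highest in KO 146 and lowest among the KO labels in KO 148, tubule means run the other way, and cell cycle means of the libraries labelled KO lie close together.

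Lists for matrix, interferon, cytoskeleton and YAP signalling also had higher values in the libraries labelled KO, in the same libraries as the glomerular markers. Of 23 matrix and fibrosis genes, 1 was called, the fibrillar collagen Col3a1, which rose from 13.8 ± 0.25 to 30.7 ± 6.07 CPM (SD, n = 3 each; log2 fold change 1.15, SE 0.15, edgeR adjusted p = 0.0357). Mmp2 had a value of 2.44 and Col5a1 of 1.5, the list median was 1.40, and 16 members were higher adjusted over the list alone. Of 29 actin and focal adhesion genes, 1 was called, Anln, an actin-binding protein of the contractile ring of dividing cells (1.39, SE 0.12, edgeR adjusted p = 0.0189). The integrin subunit Itga3 stood at 1.6 and Tpm4 at 1.18, the median was 0.54, and 6 members were higher and 1 lower adjusted over the list alone. All 23 interferon response genes were positive with a median of 0.81, with Ifit1 at 1.48, Gbp3 at 1.06 and Bst2 at 1.19. Of 27 YAP/TAZ targets, 22 were positive with a median of 0.57. Birc5, an inhibitor of apoptosis that also acts in mitosis, had a value of 1.22, Amotl1 of 1.77 and the matricellular gene Ccn2 of 1.66 (SE 0.39, edgeR adjusted p = 0.0755). Ccn1 and Ankrd1, YAP targets named in every case, had log2 fold changes of 0.08 (adjusted p = 0.763) and -0.24 (adjusted p = 0.555). Of 25 genes of the PIX, GIT and PAK complex and of Cdc42 and Rac1 signalling, 21 were positive with a median of 0.21, with Arhgap31 at 1.69, Nck2 at 0.70 and Cdc42ep1 at 1.03.

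Over all tested genes, edgeR called 0 interferon, 0 YAP/TAZ and 0 PIX list members. At an unadjusted p below 0.05 these lists had 22, 16 and 6 members higher and 0, 1 and 1 lower. Adjusted over the list alone, 22, 11 and 0 were higher and 0 were lower. DESeq2 called 19, 10 and 4 members higher and limma-voom 0. Without KO 146 edgeR called 16, 11 and 4 higher and 0, 2 and 0 lower, and without KO 148 it called 20, 12 and 5 higher. With any other library left out it called 0 in these lists. In the matrix and actin lists DESeq2 called 17 and 10 higher and 0 and 1 lower, and limma-voom called 0 and 1 higher. For these 2 lists edgeR called 15 and 16 higher and 0 and 1 lower without KO 146, and 15 higher in each without KO 148. It called 0 in both with any other library left out. Without KO 146 the medians of the matrix, actin, YAP/TAZ and PIX lists fell to 0.90, 0.28, 0.31 and 0.07, and 17 of 25 PIX members were positive. The interferon median was then 0.55, with 22 of 23 members positive. Camera called the matrix, actin, interferon, YAP/TAZ and PIX lists higher (adjusted p = 5.34e-09, 7.76e-06, 1.71e-11, 2.10e-04 and 0.015). With an estimated correlation the adjusted p values were 0.45, 0.553, 0.488, 0.538 and 0.664, and by fry 0.0981, 0.174, 0.148, 0.159 and 0.24. Scaling by library totals gave a PIX median of 0.35. Proximal tubule content did not overlap between the groups, at 10.28 to 10.36 log2 CPM in the libraries labelled CTRL and 9.28 to 9.97 in those labelled KO. Values with it as a covariate are therefore an extrapolation. With proximal tubule content as a covariate the direction turned to lower for the PIX, actin and YAP/TAZ lists (camera adjusted p = 0.013, 0.0109 and 0.331). The interferon list was no longer called (adjusted p = 0.105, range over alternatives 1.45e-15 to 0.488) and its median was 0.19, and the matrix list stayed called with a median of 0.15 (adjusted p = 5.04e-05, range 7.61e-16 to 0.45). Over all alternatives the adjusted p ran from 0.00587 to 0.664 for the PIX list, with 0.127 without KO 146, from 6.57e-08 to 0.553 for the actin list and from 2.61e-05 to 0.538 for the YAP/TAZ list.

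Genes of cholesterol synthesis were lower in the libraries labelled KO. Of 19 members, 4 were lower, 0 were higher and 15 did not pass, with 7 lower adjusted over the list alone and a median of -0.29. Idi1, an isomerase of the mevalonate pathway, went from 22.0 ± 1.84 to 12.1 ± 0.50 CPM (SD, n = 3 each; -0.87, SE 0.099, edgeR adjusted p = 0.0311). Insig1, a sterol-regulated membrane protein, changed by -0.72 (SE 0.09, adjusted p = 0.0332) and Msmo1, a sterol oxidase, by -0.54 (SE 0.075, adjusted p = 0.0371). The fourth, Sc5d, named after its value was seen, changed by -0.54. Camera gave an adjusted p = 1.34e-07, or an adjusted p = 0.197 with an estimated correlation, and fry gave 0.0137. Without CTRL 157, 162 or 163 or KO 147 edgeR called 0 members, and without KO 146 and KO 148 it called 9 and 8, while the median stayed between -0.36 and -0.25. Scaling by library totals left 0 members called, with a median of -0.17 and 1 positive. Tubule lists had lower and podocyte, endothelial and mesangial lists higher values in the same libraries. With either content covariate the cholesterol median was -0.14, with 4 members lower.

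Nuclear genes of oxidative phosphorylation had small negative values. All 24 were negative with a median of -0.23, including Sdha (-0.44, SE 0.14), Ndufs1 (-0.38, SE 0.13) and Etfa (-0.43, SE 0.15). edgeR called 0 over all tested genes and 0 adjusted over the list alone, 3 were lower at an unadjusted p below 0.05, DESeq2 called 1 lower and limma-voom 0. Without KO 146 the median was -0.10 and 3 of the 24 were positive, and with library totals it was -0.10 and 2 were positive. Camera called the list lower (adjusted p = 1.51e-04), with an adjusted p = 0.651 with an estimated correlation and 0.251 by fry. With proximal tubule content as a covariate the list was called higher (camera adjusted p = 2.97e-05, range over all alternatives 1.45e-05 to 0.651). That covariate did not overlap between the groups, so the turn rests on an extrapolation.

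**Figure D3:**
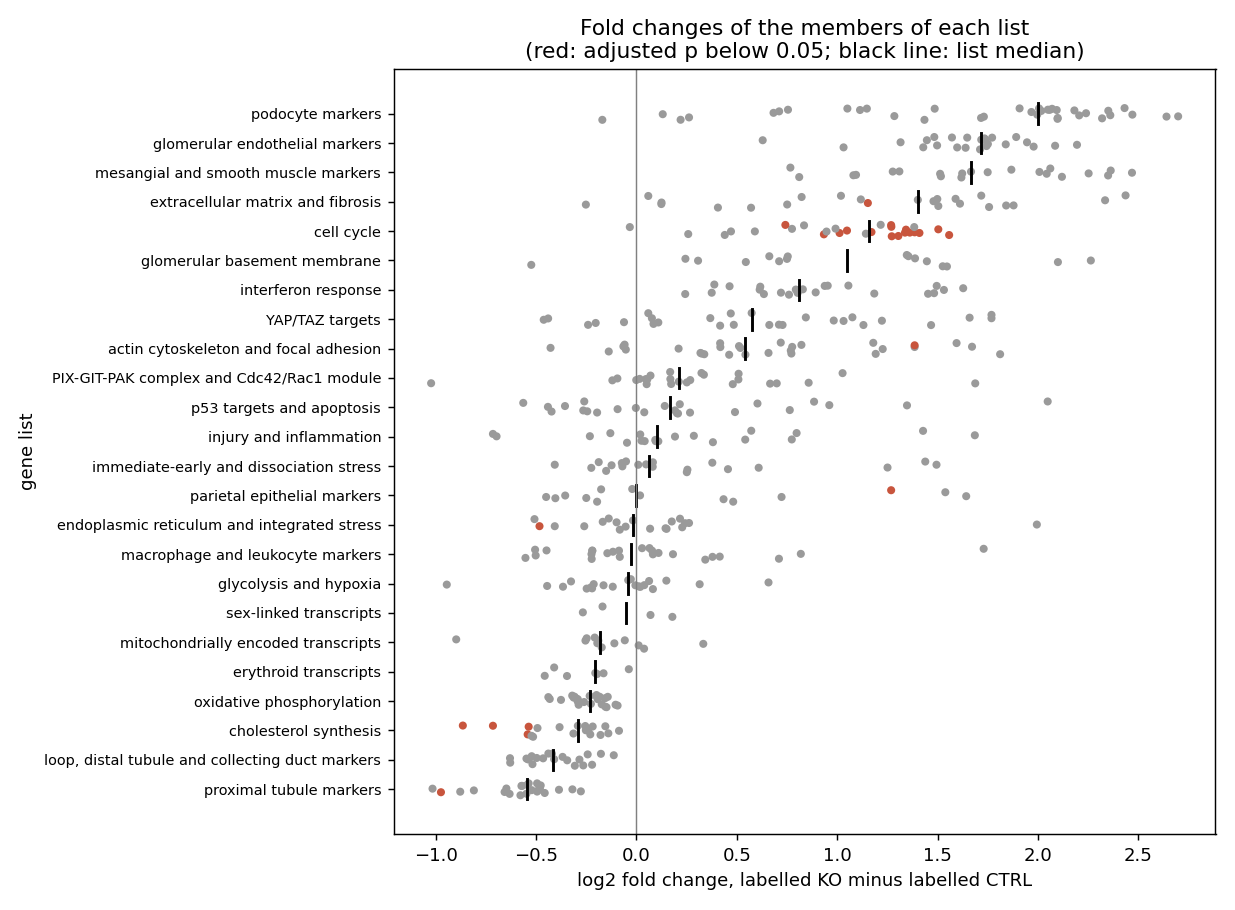
Log2 fold changes, labelled KO minus labelled CTRL, of the tested members of all 24 lists, with a black line at each list median and red points for genes with an edgeR adjusted p below 0.05. Red points cluster in the cell cycle list on the positive side and the cholesterol synthesis list on the negative side, while the podocyte list has the highest median, 2.0, with no red point.

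The other 10 lists were not called by camera. Of the parietal epithelial markers 1 of 14 was called higher, Ncam1, a cell adhesion molecule (1.27, edgeR adjusted p = 0.0311), and of the endoplasmic reticulum stress genes 1 of 19 was called lower, Edem1, a factor for degradation of misfolded proteins (-0.48, edgeR adjusted p = 0.0485); both are named after their values were seen. Adjusted over the list alone, 4 parietal markers were higher, and 1 stress gene was higher and 3 were lower. In the 8 remaining lists edgeR called 0 members over all tested genes. Counts at an unadjusted p below 0.05 were 1 higher and 4 lower of 24 leukocyte markers, 1 lower of 7 erythroid transcripts, 6 higher and 3 lower of 24 p53 targets, and 5 higher and 1 lower of 20 injury genes. They were 5 higher of 20 immediate-early genes, 1 higher and 3 lower of 21 glycolysis genes, 0 of 12 mitochondrially encoded transcripts and 1 lower of 4 sex-linked transcripts. Adjusted over the list alone, 2 p53 targets, 3 injury genes and 2 immediate-early genes were higher, 1 injury gene and 1 glycolysis gene were lower, and the leukocyte, erythroid, mitochondrial and sex-linked lists had 0. DESeq2 called 1 leukocyte marker higher and 2 lower, 4 p53 targets higher and 1 lower, 3 injury genes higher and 1 lower, 3 immediate-early genes higher, 1 glycolysis gene higher and 1 lower, and 0 in the other 3 lists, and limma-voom called 0 in all 8.

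Camera adjusted p values of these 10 lists ran from 0.14 to 0.616. Medians were -0.03 for leukocyte markers, -0.21 for erythroid transcripts, 0.17 for p53 targets, 0.10 for injury genes, 0.07 for immediate-early genes, -0.04 for glycolysis, -0.18 for mitochondrially encoded transcripts and -0.05 for sex-linked transcripts. The median and the mean differed in sign for the parietal (-0.002 and 0.304), leukocyte (-0.028 and 0.067) and endoplasmic reticulum stress lists (-0.017 and 0.067). With library totals as the scaling the medians of the parietal, leukocyte, stress, glycolysis and sex-linked lists were 0.12, 0.11, 0.12, 0.09 and 0.10, so no direction is given for them. Nor is one given for the erythroid, mitochondrially encoded and immediate-early lists, whose medians were 0.06 without CTRL 162, 0.05 without KO 146 and -0.01 without CTRL 157, or for the p53 list (0.05 without KO 146) and the injury list (0.06 without KO 146, 0.21 without KO 147). Without CTRL 163 camera called the erythroid list lower (adjusted p = 2.84e-04, range over alternatives 2.84e-04 to 0.939), without CTRL 162 the immediate-early list higher (adjusted p = 0.0308, range 0.0308 to 0.734) and without KO 148 the mitochondrially encoded list lower (adjusted p = 0.0283, range 1.47e-12 to 0.737). With proximal tubule content as a covariate camera called 4 of these lists, the parietal (adjusted p = 0.00641), glycolysis (0.00943) and mitochondrially encoded (1.47e-12) lists higher and the endoplasmic reticulum stress list lower (0.0374). These calls rest on the same extrapolation between groups. Over alternatives the adjusted p ran from 0.00641 to 0.557 for the parietal, 0.00943 to 0.685 for the glycolysis and 0.0282 to 0.737 for the stress list.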

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

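Reads in no annotated feature, which the comparisons do not use, took a larger share of all counted records in the libraries labelled KO, at 3.27% ± 0.18, than in those labelled CTRL, at 2.66% ± 0.13 (SD, n = 3 each, exact permutation p = 0.1, the smallest this design allows). The share was 3.41%, 3.32% and 3.07% in KO 146, 147 and 148 and 2.6%, 2.81% and 2.57% in CTRL 157, 162 and 163. Among the lines that name no gene, this was the only line whose groups did not overlap. The exact permutation p was 0.9 for ambiguous reads, unaligned reads and reads that aligned to several places. Shares for low alignment quality overlapped as well. A line picked because its groups do not overlap always has the smallest p, so that p adds no evidence.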

How the results depend on the processing

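The glomerular covariate and the restriction to protein-coding genes were chosen after the results were seen. All 173 calls kept their sign in every alternative that tested them, including 164 tested with at least 1 CPM in 3 libraries and 156 with protein-coding genes only, while their number moved. All 173 had groups that did not overlap, so leaving out 1 library could hardly reverse a sign. The 2-fold minimum and the protein-coding restriction reuse the same fold changes. edgeR gave 173 calls (101 higher, 72 lower), and 2 to 3211 with 1 library left out (1 to 2266 higher, 1 to 1147 lower). Of the 173, it kept 2, 2 and 7 without CTRL 157, 162 and 163, 2 without KO 147 and all without KO 146 or 148. DESeq2 gave 2874 (1986 higher, 888 lower) and kept 172 of the 173. No filter gave 960 (497 higher, 463 lower), and kept 169. The proximal tubule covariate gave 190 higher and kept 99, the glomerular covariate gave 315 in all with 249 higher and kept 122, and a 2-fold minimum gave 40 lower and kept 131. Library totals in place of TMM gave 114 higher and 50 lower and kept 135, and limma-voom kept 133. The cause of these moves was not tested.

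Arhgef7 turned to -0.42 with the tubule covariate and -0.40 with the glomerular one, and ran from -0.07 to 0.28 with 1 library left out. Other named genes that changed sign were never called by the edgeR fit to all 6 libraries. They were Ccn1 (-0.10 to 0.19 with 1 library left out), Cdc42ep1 (-0.03 and -0.01 with the tubule and glomerular covariates), Tpm4 (-0.01, tubule) and Etfa (0.02 and 0). Over all alternatives, values of the named genes other than Arhgef7 kept direction and side of the threshold in 613 cases, lost the call in 131, gained it in 118 and changed sign in 6.

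Of 14 called lists, 0 stayed called with an estimated correlation (0 higher, 0 lower) and 2 by fry (1 higher, 1 lower). With the tubule covariate camera turned the PIX (adjusted p = 0.013), mesangial (0.196), YAP/TAZ (0.331) and actin (0.0109) lists to lower and the distal tubule (0.139) and oxidative phosphorylation (2.97e-05) lists to higher. With the glomerular covariate it turned the PIX (0.0223), YAP/TAZ (0.452) and actin (0.0223) lists to lower and the distal tubule (0.216) and oxidative phosphorylation (1.23e-04) lists to higher. Neither covariate overlapped between the groups, so these turns rest on an extrapolation, and their cause was not tested. Leaving out 1 library ended the camera call of 1 list, the PIX list without KO 146. No paired analysis was possible because the groups share no replicate numbers. Depth limits the genes with few counts, such as Gm4864 with 0 or 1 counts per library labelled CTRL.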

Other observations

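The tests of exchanged labels, tubule material, podocytes alone and leukocytes were chosen only after the result they bear on was seen. H19, an imprinted RNA of fetal tissue that is silenced after birth, was named after its value was seen. It had 5, 13 and 20 counts in CTRL 157, 162 and 163 and 450, 120 and 158 in KO 146, 147 and 148 (log2 fold change 3.94, SE 0.57, edgeR adjusted p = 0.0397). A list of 11 other perinatal growth and imprinted genes, written before its values were seen, had 9 tested members, all positive, with a median of 0.83 (camera p = 4.41e-04, or p = 0.139 with an estimated correlation). Without KO 146 the median was 0.34 and 8 of the 9 were positive. Mest and Gpc3, picked from it after their values were seen, had values of 2.07 and 1.14 (edgeR adjusted p = 0.0666 and 0.0731), and no member was called by limma-voom or by the filtered edgeR fit to all 6 libraries, while DESeq2 called 4, and edgeR called 1 without the filter, 3 without KO 146 and 4 without KO 148. Azgp1, a secreted zinc-binding glycoprotein also named after its value was seen, fell from 2.39 ± 0.52 to 0.101 ± 0.016 CPM in the libraries labelled KO (SD, n = 3 each; log2 fold change -4.51, edgeR adjusted p = 0.00612).

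With the glomerular endothelial and mesangial means as a covariate, camera called 4 lists that it did not call without it. Mitochondrially encoded transcripts had a median of 0.55 with 4 of 12 members higher (camera adjusted p = 3.72e-12, range over alternatives 1.47e-12 to 0.737), against a median of -0.18 with 0 called without it. Matrix genes had a median of 0.15, against 1.40 without the covariate, with 5 members higher (adjusted p = 2.34e-06, range 7.61e-16 to 0.45). Parietal epithelial markers had a median of 0.12 with 2 members higher (adjusted p = 0.00718, range 0.00641 to 0.557). Glycolysis genes had a median of 0.15 with 1 member higher (adjusted p = 0.0223, range 0.00943 to 0.685), and endoplasmic reticulum stress genes a median of -0.17 with 1 higher and 2 lower (adjusted p = 0.0282, range 0.0282 to 0.737). Cholesterol synthesis genes had a median of -0.14, against -0.29 without the covariate, with 4 lower (adjusted p = 5.09e-05, range 1.14e-08 to 0.197). The podocyte and basement membrane lists also stayed called higher (camera adjusted p = 1.09e-04 and 0.0285). Their medians were 0.26 and 0.07, with 27 of 36 and 10 of 16 members positive and 1 and 4 called higher. The covariate is itself measured in these libraries and differs between the groups, by 1.46 on the log2 scale (exact permutation p = 0.1, the smallest possible), so these values rest on an extrapolation between groups.

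Podocyte, endothelial and mesangial markers had higher values in the libraries labelled KO, though the edgeR fit to all 6 libraries called 0 of them. Without KO 146 edgeR called 32, 19 and 17 of them, without KO 148 32, 25 and 17, and with any other library left out 0. The lists of these markers were not called with an estimated correlation (camera adjusted p = 0.488 each) or by fry (0.159 each), over a range of alternatives from 7.54e-37 to 0.905. A change in podocytes alone is argued against by the endothelial list, whose median log2 fold change was 1.72. A candidate explanation is more tubule material in the libraries labelled CTRL, since both tubule lists had lower values and the podocyte mean relative to endothelial and mesangial cells differed by 0.04, within the SD of 0.13. Without the 5 podocyte markers that tubules also express that difference was 0.19 against an SD of 0.15. With the endothelial and mesangial means as a covariate, an extrapolation between groups, camera called the podocyte and basement membrane lists higher (adjusted p = 1.09e-04 and 0.0285). Relative to the endothelial and mesangial mean, though, the basement membrane mean was lower, at 0.78 ± 0.4 in the libraries labelled KO against 1.3 ± 0.07. A small podocyte excess therefore stays open, as does an effect of bPIX loss, which was not tested apart from the groups. Exchanged genotype labels cannot be told apart from correct ones, because Arhgef7 differed by 0.17 with an SE of 0.17, and although it was lower relative to the podocyte mean in the libraries labelled KO, at -0.10 ± 0.45 against 1.26 ± 0.17 (SD, n = 3 each, exact permutation p = 0.1, the smallest possible), and relative to the endothelial and mesangial mean, at 0.49 ± 0.58 against 1.80 ± 0.08, a gene that does not follow these markers falls relative to them under either labelling.

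Of 28 cell cycle genes, edgeR called 16 higher in the libraries labelled KO, with a camera adjusted p = 0.124 with an estimated correlation. Leaving out CTRL 157, CTRL 162 or KO 147 left 0 called. A larger share of glomerular cells as the whole cause is argued against, since KO 146 and KO 148 had endothelial and mesangial means of 7.18 and 5.40 log2 CPM but cell cycle means of 3.84 and 3.97. With that content as a covariate the cell cycle median was 1.31, against 1.16 without it. The covariate extrapolates between groups, and relative to the endothelial and mesangial mean the cell cycle mean was not higher, at -1.80 ± 0.03 in the libraries labelled CTRL and -2.24 ± 0.99 in those labelled KO (SD, n = 3 each, exact permutation p = 0.7), so a part played by glomerular share stays open. Leukocytes are argued against by their list, with a median of -0.028 and an upper quartile of 0.222, and by Cd74, an abundant gene chosen after its values were seen, at 125 CPM in the libraries labelled CTRL and 91.6 CPM in those labelled KO. A younger stage of the mice labelled KO, all given as 3 weeks old, may contribute and cannot be told apart from other causes, since the growth list had higher values without the covariate, with a p = 0.139 with an estimated correlation and a median of 0.34 without KO 146, and a median of 0.26 and a camera p of 0.649 with it. The cell type in which cell cycle genes were higher was not tested, and tubule transcripts were abundant in every library. Relative to the proximal tubule mean, the cell cycle mean was -7.39 ± 0.13 in the libraries labelled CTRL and -5.76 ± 0.29 in those labelled KO (exact permutation p = 0.1). The proximal tubule mean itself differed, so this value does not place the change in a cell type. An effect of bPIX loss on proliferation stays open as a hypothesis that was not tested apart from the labels.

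Among the called genes, 7 were processed pseudogenes, 5 higher and 2 lower in the libraries labelled KO, such as Gm6969 (19, 23 and 24 counts in CTRL 157, 162 and 163, 802, 701 and 771 in KO 146, 147 and 148) and Gm12751 (261, 214 and 269 against 7, 6 and 9). Gm7240 had 44, 38 and 19 counts in the libraries labelled CTRL and 0 in each labelled KO, where a count of 0 allows up to 3. Parallel changes in their parent genes are argued against, since the median absolute log2 fold change of the parents was 0.105 and the largest 0.284, against 3.12 for the smallest pseudogene change. Parents were the best sequence matches, at 86.6% to 100% identity. Hdac1 was the match of both Gm10093 and Gm4864 and so entered more than once. Zfp808, the match of Gm7240, had the lowest identity and stood at only 0.974 and 1.02 CPM in the libraries labelled CTRL and KO. Cox7a2l and Polr1d, parents of Gm6969 and Gm12751, changed the opposite way (-0.209 and 0.245), while Thrap3, parent of Gm5898, changed the same way (0.105). No parent was called (lowest edgeR adjusted p = 0.162). The comparison does not cover reads assigned to a different copy. The labelled split separated 5 processed pseudogenes without overlap by 8-fold or more and the highest of the other 9 splits separated 2, but any cause linked to the groups would give this. Alleles that differ between the parents of the groups therefore cannot be told apart from other such causes, as strain and litter are not given in the sources used here.

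The count of 173 called genes was compared with all 10 splits of the 6 libraries into 3 and 3. The labelled split alone, 1 of 10, gave as many, and the highest of the others gave 3, but 10 splits are too few for a share under 0.05.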
